A study of Drosophila melanogaster with 4 samples.

How the data were processed

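Sorted neuroblast nuclei of Drosophila melanogaster embryos were profiled for H3K27me3 and H3K27ac in Cut knockdown and control embryos, with 1 library for each of the 4 combinations. Per the labels' protocols, embryos were collected for 16 h at 25 °C and fixed with formaldehyde, and dsRed-positive nuclei (wor-gal4 driving UAS-dsRed) were sorted. Chromatin was cut with 15 U of micrococcal nuclease and sonicated for 3 min. Immunoprecipitation used 2 µg of the H3K27me3 antibody or 1 µg of the H3K27ac antibody, and input DNA was the control. The labels give the same catalogue number for both antibodies, and whether that is a slip was not settled here. If it is not, the 2 marks were not measured with different antibodies, and the overlap of their lists would not compare 2 marks. In the control, H3K27me3 covered 113 kb of the bithorax region and H3K27ac 41.6 kb, although the H3K27me3 list was the shorter. For that region this argues against 1 antibody. Libraries were sequenced as single ends on a HiSeq2500. Per the submitters' processing notes, the tools were FastQC, Bowtie2, MACS2 and SICER and the build was dm6. Their versions, their roles, the peak threshold, the treatment of duplicate reads and the number of reads are not given in the sources used here. Micrococcal nuclease cuts open chromatin more readily than closed chromatin, so the yield of fragments can differ between them.

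The deposited files are MACS2 broad peak lists, called by the authors for each library separately, with no header. Start and end are 0-based in the files and are given 1-based here. The deposited score of each peak equals 10 times the -log10 q, cut to a whole number, in 75206 of the peaks and differs in 2. The fold enrichment of each peak over background is the authors' deposited ratio, and the -log10 p and -log10 q values are likewise as deposited. The lowest -log10 q was close to 1 in each list (1.01 in all 4), so the lists share a lower bound. Fold and -log10 q were used to describe, rank and filter peaks within a list, since ranks from lists of different lengths show no change. Where folds of 2 libraries are set side by side, as at rpr, their scales may differ. Peak calls hold no counts, so the depth per library is unknown and the precision that depth would give cannot be stated. A deeper library gives more and longer peaks at the same threshold, and each covered length here carries that uncertainty. Regions without a peak are below the authors' threshold, not free of the mark.

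Peaks on the 6 arms 2L, 2R, 3L, 3R, 4 and X were kept, and peaks on Y were set aside. Overlapping peaks of a list were merged to get covered length, and a peak was called shared when at least 1 bp overlapped. Shares of peaks and genes have 95% exact Clopper-Pearson intervals, which cover counting error only. Gene spans of 13922 protein-coding genes came from a RefSeq gene table of the same assembly, release 6. That table gives neither strand nor transcript starts. The plan to call H3K27ac in windows around transcript starts was therefore replaced, after the table was seen, by a peak that overlaps the gene span extended by 500 bp on either side. A gene was called for H3K27me3 when peaks covered at least 50% of its body. The gene called SA1 here is the cohesin subunit SA.

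The comparisons, the gene lists and the rule for named genes were fixed before the data were examined. Named genes were the genes ct, rpr, grim, hid, skl, Ubx, abd-A, Abd-B, SA1 and N, and the 10 genes with the largest gain and the 10 with the largest loss of H3K27me3 cover in kb. They were also the 10 genes with H3K27ac only in the knockdown and the 10 only in the control with the highest peak fold and no peak of the other library within 1 kb, and up to 4 gained or lost genes of each list. Genes without an official symbol count in these ranks and may go unnamed. Other list members named in the text were chosen after their values were seen. The 16 lists are cut and cohesin, cell death activators, cell death machinery, Hox genes, Notch pathway, neuroblast identity, temporal series, neuroblast spatial patterning, Polycomb group, Trithorax group and acetylation, housekeeping genes, and markers of neurons, glia, muscle and mesoderm, epidermis and trachea, and gut, blood and fat. Of 278 symbols in the lists, 276 matched the gene table, and the other 2, Dl and calypso, were not analysed here. The neuroblast identity and temporal series lists share members such as cas, D and grh.

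With 1 library per group, no test across conditions was made. For each list and mark the mean difference of covered share, knockdown minus control in percentage points, was placed among 10000 random gene sets of the same size, matched in 5 bins of gene length and 4 bins of the mean cover of the control and the knockdown. Overlap of the 2 marks was set beside 1000 circular shifts of 1 list along each arm. The window analysis between grim and rpr moved a window of 93117 bp along the arms in steps of 10 kb. Windows with a control cover within 20% of that of the interval, taken from left to right without overlap, were counted with both lists at the same covered length. Alternatives were peaks with -log10 q of at least 2, peaks with a fold of at least 2, the longer list reduced to the covered length of the shorter by its highest folds, other overlap and gene body bounds, merging of peaks less than 1 kb apart, all sequences, and other matching of random sets. Lists without the H3K27me3 peaks or bases shared with H3K27ac, and calls at gene ends, were added after the data were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated data for the H3K27me3 gene calls over 13922 genes, 200 of 200 planted gains were recovered, and the 32 other genes called overlapped a planted gene. Cover differed from a base-by-base count in 0 of 500 queries. Of 200 random lists with no planted change, 7 fell outside the 2.5th to 97.5th percentile, and a planted list lay at the 100th. These lists used differences simulated independently for each gene. They do not show how the percentiles behave for neighbouring genes that share cover.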

Results

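Chromatin marks were profiled in sorted neuroblast nuclei of Drosophila melanogaster embryos in which Cut was knocked down by RNA interference, and in control embryos. Neuroblasts are the stem cells of the fly nervous system, and Cut is a homeodomain transcription factor encoded by the gene ct. The study asks how Cut, together with cohesin, the ring complex that holds sister chromatids and shapes chromatin loops, acts on chromatin where neuroblasts die. Nuclei carried dsRed driven by wor-gal4 and came from embryos collected over 16 h at 25 °C. Per the labels, the sorted nuclei were 0.5 to 3% of all embryonic nuclei and at least 50% of them were positive by microscopy. Chromatin immunoprecipitation and sequencing were carried out for H3K27me3, the histone mark of Polycomb repression, and for H3K27ac, a mark of active promoters and enhancers. The series held 4 libraries, 1 for each mark in each genotype. No difference between genotypes therefore has a replicate check, no p-value is given, and values are set side by side. Peak lists were analysed and the read depth behind them is unknown, and depth enters every covered length given here. On the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X, build dm6), the H3K27me3 lists held 4238 peaks in the control and 18692 in the knockdown. The H3K27ac lists held 25941 and 25519 peaks. The targeted gene, ct (X:7608428-7678859), had H3K27me3 over 2.49 kb in the control and 5.36 kb in the knockdown, and H3K27ac over 1.01 and 2.42 kb. Peak lists measure no transcript, and the extent of the knockdown was not analysed here.

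To ask where the repressive mark differed after Cut knockdown, the H3K27me3 cover of genes was compared between the 2 lists. The largest differences were of more cover in the knockdown. Ptp61F, which encodes a tyrosine phosphatase, had 4.62 kb covered in the control and 47.3 kb in the knockdown, and the homeotic gene Antp had 21.7 and 53.3 kb. The values were 2.44 and 32.5 kb for dpy, which encodes a giant protein of the apical extracellular matrix, and 2.01 and 31.4 kb for pros, the homeodomain factor that moves into the nucleus of neuroblast daughters. They were 5.83 and 32.8 kb for bru3 and 2.16 and 27.9 kb for jing. The long pericentromeric genes Myo81F (73.5 and 127 kb) and Pzl (31.2 and 60.2 kb) were also among the 10 largest gains. At the other end, the mucin genes Muc68E (3.98 kb) and Muc30E (2.06 kb) had H3K27me3 in the control and none in the knockdown, as did beat-IIb (2.10 kb), naz (1.86 kb) and Stlk (1.83 kb). Haspin, a histone kinase gene, had 4.54 kb in the control and 0.971 kb in the knockdown, l(3)80Fj had 2.57 and 0.298 kb, and Tg, which encodes transglutaminase, had 2.43 and 0.474 kb. Like Myo81F and Pzl, Haspin and Stlk (2R:4014111 and 2R:4546691) and l(3)80Fj (3L:27967244) lie toward the centromere.

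Of 13922 protein-coding genes, 222 had at least 50% of the gene body under H3K27me3 in both lists. A further 1930 genes met that bound only in the knockdown (13.9%, 95% exact Clopper-Pearson interval 13.3 to 14.4%) and 62 only in the control (0.445%, 0.342 to 0.571%). These intervals, and those below, cover counting error only. The H3K27me3 peaks covered 4.68 Mb in the control and 19.5 Mb in the knockdown, a ratio of 4.16, with length-weighted mean fold enrichments of 1.88 and 1.96. Peak fold enrichments are the authors' deposited values throughout. The ratio was above 1 on each of the 6 arms, from 1.53 on chromosome 4 to 4.88 on X. Of the control peaks, 59.7% (58.3 to 61.2%) overlapped a knockdown peak, and the share was 84.6% (82.3 to 86.7%) among the 1060 widest, of at least 1251 bp. Since 1 bp of overlap sufficed, a wide peak meets this rule more readily. By bases, 54.9% of the control cover lay in knockdown peaks, against a mean of 15.2% over circular shifts. Of the knockdown peaks, 13.0% (12.5 to 13.5%) overlapped a control peak. When H3K27me3 peaks that overlapped an H3K27ac peak of either genotype were left out, the covered ratio was 1.32 (2.40 when only the bases inside H3K27ac peaks were left out), with 54 genes covered only in the knockdown and 27 only in the control. When the knockdown list was held to the covered length of the control list, these counts were 260 and 197.

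**Figure D1:**
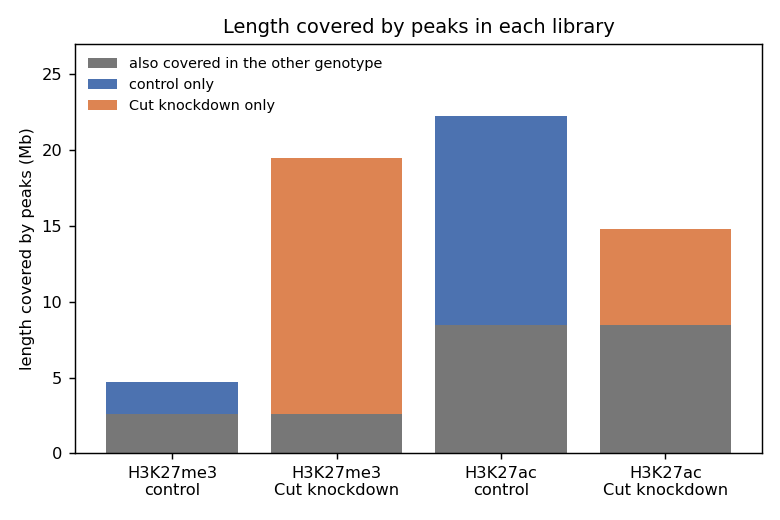
Length covered by peaks (y axis, Mb) in each of the 4 libraries (x axis), divided into bases that the other genotype's list of the same mark also covers and bases covered in that genotype only. H3K27me3 covered 4.68 Mb in the control and 19.5 Mb in the knockdown, and H3K27ac 22.2 and 14.8 Mb.

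The cell death locus on 3L holds hid, grim, rpr and skl, whose products block the inhibitors of apoptosis and so start cell death. From hid to skl (3L:18167745-18439942, 272 kb), H3K27me3 covered 30.2 kb in the control and 35.0 kb in the knockdown, and H3K27ac 11.4 and 8.82 kb. The difference in H3K27me3 was not of 1 direction along the locus. Between grim and rpr (3L:18304418-18397534, 93.1 kb that hold none of the 4 genes), the mark covered 15.2 kb in the control and 9.16 kb in the knockdown, a difference of -6.09 kb, whereas between hid and grim it covered 8.71 and 16.2 kb and between rpr and skl 5.05 and 7.85 kb. At rpr itself (3L:18397535-18398435) the knockdown list had a peak at 3L:18397811-18398736 with a fold enrichment of 3.38, the second highest of that list's 18692 peaks by fold and the highest by -log10 q (11.3). The control peak there (3L:18397964-18398245) spanned 282 bp with a fold of 1.88. The highest fold was 3.61 in the knockdown list and 2.85 in the control list, and the medians were 1.89 and 1.86. Folds of the 2 libraries may thus differ in scale at the top. The body of rpr was covered over 0.282 kb in the control and 0.625 kb in the knockdown, and that of grim over 0.229 and 0.734 kb. For hid the values were 0.695 and 0.397 kb, and skl had no peak of either mark in either genotype. No H3K27ac peak lay on rpr, grim had 0.146 kb in the knockdown only, and hid had 1.68 kb in the control and 0.771 kb in the knockdown. The grim to rpr difference kept its sign in the alternatives tried but ranged from -0.576 kb with peaks of -log10 q of at least 2 to -11.9 kb with both lists at the same covered length. Over the whole locus both differences changed sign with the setting: that of H3K27me3 was -13.4 kb at the same covered length, and that of H3K27ac was 1.42 kb there and 3.16 kb with peaks of a fold of at least 2. The same covered length was reached by trimming the longer list alone. It could therefore only lower the H3K27me3 differences, that from grim to rpr included, and only raise those of H3K27ac. A fold of 2 was passed by 32.6% of control and 80.3% of knockdown H3K27ac peaks, so it too favours the knockdown.

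**Figure D2:**
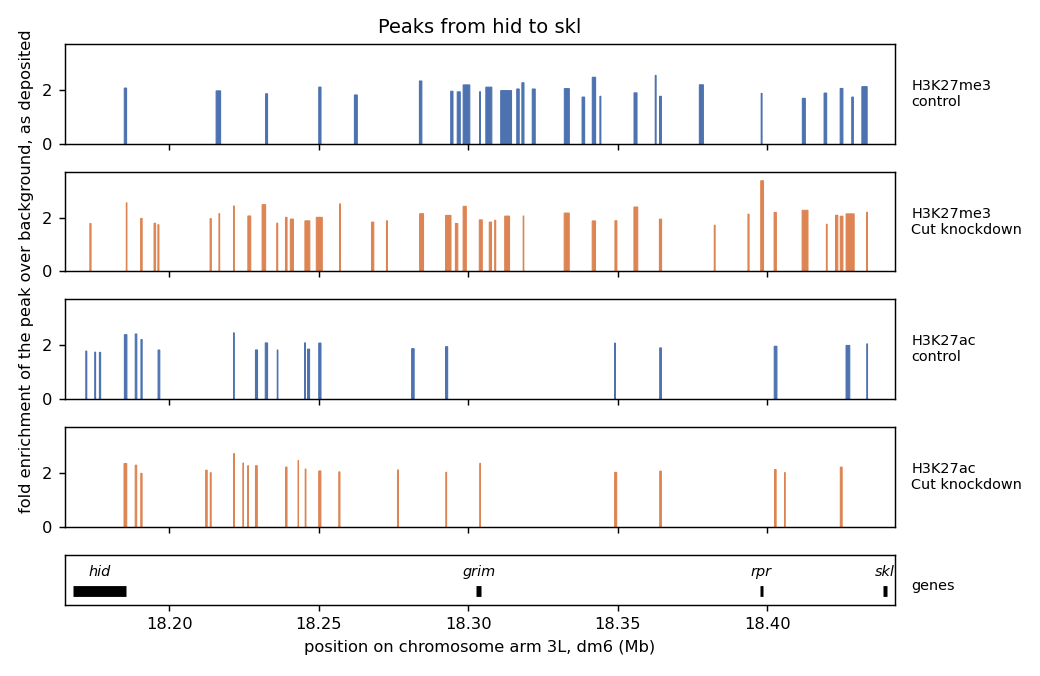
Peaks of the 4 libraries from hid to skl (x axis, position on 3L in Mb, build dm6). Bar height is the deposited fold enrichment of each peak and bar width its extent, outlined with a thin line so that narrow peaks show, with the 4 genes drawn underneath. The knockdown H3K27me3 peak at rpr stands at 3.38 against 1.88 in the control.

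The Hox genes, which set segment identity and are long-standing Polycomb targets, had more H3K27me3 cover in the knockdown list for all 8 members. In the bithorax region (3R:16656623-16972236) the mark covered 113 kb in the control and 188 kb in the knockdown, and in the Antennapedia region (3R:6661427-6999228) 87.9 and 159 kb. Among the genes, Ubx (17.1 and 46.0 kb) and Antp (21.7 and 53.3 kb) differed most. Abd-B, already covered over 24.3 kb in the control, had 25.8 kb in the knockdown, and abd-A had 8.70 and 13.0 kb. The values were 9.01 and 10.4 kb for lab, 7.83 and 15.5 kb for pb, 5.25 and 7.25 kb for Dfd, and 10.5 and 13.5 kb for Scr. H3K27ac covered 41.6 kb of the bithorax region in the control and 30.7 kb in the knockdown, and 49.3 and 36.8 kb of the Antennapedia region. Without the H3K27me3 peaks that overlapped H3K27ac, the differences between the genotypes were -1.22 kb for the bithorax and -3.83 kb for the Antennapedia region, whereas leaving out only the bases inside H3K27ac peaks gave 52.0 and 34.1 kb. The H3K27ac differences turned positive with peaks of fold enrichment of at least 2 (10.8 and 18.0 kb). That bound kept 32.6% of control and 80.3% of knockdown H3K27ac peaks and so favours the knockdown.

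**Figure D3:**
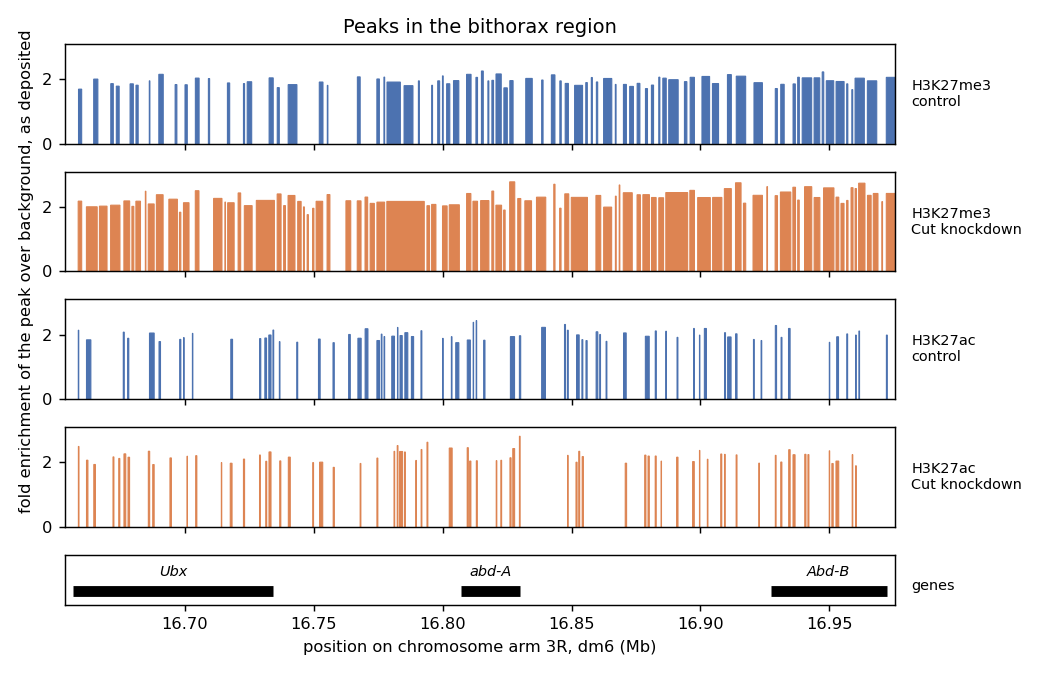
Peaks of the 4 libraries across the bithorax region (x axis, position on 3R in Mb, build dm6), with the deposited fold enrichment as bar height, a thin outline so that narrow peaks show, and Ubx, abd-A and Abd-B drawn underneath. H3K27me3 covered 17.1 kb of Ubx in the control and 46.0 kb in the knockdown, and 24.3 and 25.8 kb of Abd-B.

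The H3K27ac lists were compared to ask which genes carried the active mark in only 1 genotype. Genes with H3K27ac in the knockdown only, ranked by the deposited fold of that peak, included PIG-Q, an enzyme gene of glycosylphosphatidylinositol anchor synthesis (3.58), the checkpoint gene Rad9 (3.43), the chaperonin gene CCT4 (3.31), the ribosomal protein gene RpL17 (3.27), Vlet (3.23), the mitochondrial ribosomal protein gene mRpL37 (3.09) and PrBP (3.05). The effector caspase gene Drice, named by its list, had a knockdown peak of 3.53 and no control peak on the gene or within 500 bp. Unlike at the genes ranked here, a control H3K27ac peak lay within 1 kb beyond that span. Genes with H3K27ac in the control only included alpha4GT2 and its neighbour Mst57Da, which shared a peak of 2.89, pan, the transcription factor of Wnt signalling (2.55), Cadps, a gene of dense core vesicle release (2.51), and dimm, a regulator of neuropeptide cells (2.48). In all, 9702 genes had an H3K27ac peak on the gene or within 500 bp of it in both lists. Another 998 (7.17%, 6.75 to 7.61%) had 1 only in the knockdown and 1448 (10.4%, 9.90 to 10.9%) only in the control. The peaks covered 22.2 Mb in the control and 14.8 Mb in the knockdown (ratio 0.667), with length-weighted mean folds of 1.95 and 2.20 and median widths of 625 and 432 bp. Of the control peaks, 58.3% (57.7 to 58.9%) overlapped a knockdown peak, and 66.3% (65.7 to 66.8%) of the knockdown peaks overlapped a control peak. Peaks with a fold of at least 2 were 32.6% of the control list and 80.3% of the knockdown list. Counting those alone, the covered ratio was 1.65, with 4438 genes marked only in the knockdown and 610 only in the control. Peaks with -log10 q of at least 2 were 19.9% of the control list and 20.1% of the knockdown list. A fold of 2 was thus the laxer bound for the knockdown list and favours it. With peaks of -log10 q of at least 2 the covered ratio was 0.776, with 2557 genes marked only in the knockdown and 1493 only in the control.

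The 2 marks were then set against each other within each genotype. Of the 1930 genes with H3K27me3 over their body only in the knockdown, 1593 had H3K27ac in both genotypes, 167 in the control only and 108 in the knockdown only. Examples are E(z), the H3K27 methyltransferase gene itself, covered by H3K27me3 over 2.76 kb in the knockdown and not in the control, and the tubulin gene alphaTub84B, covered over 1.37 kb in the knockdown only, with H3K27ac over 2.24 kb in the control and 1.75 kb in the knockdown. In the control, 26.5% of H3K27me3 bases lay in H3K27ac peaks, against a mean of 17.3% over 1000 random circular shifts (lowest 15.3%, highest 19.3%). In the knockdown, 33.3% did, against a mean of 11.3% (lowest 10.7%, highest 12.4%). The observed overlap was thus 1.53 and 2.94 times that of the shifts. At peaks with -log10 q of at least 2 the genotypes did not stand apart, at 3.78 in the control and 3.84 in the knockdown. With the lists of each mark at the same covered length they did, at 1.38 and 2.18. The knockdown value was also the higher with peaks of a fold of at least 2. By genes, of which 80.1% in the control and 76.9% in the knockdown had H3K27ac, those called for both marks were 1.05 and 1.13 times the product of the shares. Among H3K27me3 peaks found only in the knockdown, 85.4% (84.8 to 85.9%) overlapped an H3K27ac peak of either genotype, against 40.6% (38.2 to 42.9%) of those found only in the control.

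Gene groups fixed before the data were examined were described by the mean share of each gene covered by H3K27me3. The 38 spatial patterning genes of neuroblasts averaged 32.8% in the control and 67.6% in the knockdown. In this group 12 genes passed the 50% bound in both, 17 only in the knockdown, among them hh (2.55 and 13.2 kb), Dll (5.65 and 15.8 kb) and mirr (3.47 and 11.2 kb), and none only in the control. The 18 temporal series genes, which time neuroblast fates, averaged 14.1 and 44.6%. Of these, hb, cas, svp, danr, slp1, slp2, D and tll passed the 50% bound only in the knockdown, though svp had 13.9 kb and slp2 1.03 kb in the control. In the 26 neuroblast identity genes the means were 4.54 and 37.0%, and 9 were covered only in the knockdown, among them SoxN (none and 3.21 kb) and cas (none and 2.84 kb). Of the 21 Notch pathway genes, 8 were covered only in the knockdown, all of them in the Enhancer of split complex, such as E(spl)m5-HLH and E(spl)m8-HLH, and Brd was covered only in the control (means 4.66 and 38.8%). Polycomb group genes averaged 1.93 and 32.2%. E(z), Su(z)12, Psc, Su(z)2, phol and Asx passed the 50% bound only in the knockdown, though Su(z)2 had 2.985 kb and Psc 1.31 kb in the control. The means were 37.4 and 56.2% for Hox genes, 12.2 and 28.7% for the 4 cell death activators, 0.644 and 21.1% for the cell death machinery, 0.294 and 20.3% for cut and cohesin, and 0.321 and 20.4% for the Trithorax group and acetylation enzymes. They were 1.82 and 13.1% for neuron, 11.5 and 36.95% for glia, 15.8 and 27.4% for muscle and mesoderm, 7.49 and 30.7% for epidermis and trachea, and 15.7 and 41.8% for gut, blood and fat markers. Housekeeping genes had none in the control and 25.3% in the knockdown.

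Each group's difference was placed among 10000 random gene sets of the same size, matched on gene length and on the mean cover of the 2 libraries, as a description of these libraries. That mean holds the knockdown value, so the matching takes up part of the difference it is used to place. Since 32 values were computed, a few beyond these bounds arise by chance. For H3K27me3 the Polycomb group lay at the 99.5th percentile (30.3 points, against a random mean of 23.3), Hox genes at the 0.61th (18.8 against 34.3 points) and muscle and mesoderm markers at the 1.36th (11.6 against 20.2 points). The other 13 groups lay between the 9.81th and the 86.9th. With sets matched on length only, 7 groups lay in the top 2.5%, against 1 as matched, none in the bottom 2.5%, and Hox genes at the 88.9th and muscle and mesoderm markers at the 14.35th. The placing of a group depended on other settings too. Spatial patterning genes, at the 10.5th percentile, lay at the 99.85th with peaks of -log10 q of at least 2, at the 99.77th with peaks of a fold of at least 2, at the 100th with random sets matched on length only and at the 1.97th without H3K27me3 peaks that overlapped H3K27ac. The Polycomb group lay at the 4.56th in that last setting, the Hox genes lay at the 53.5th with peaks of -log10 q of at least 2, and the muscle and mesoderm markers at the 56.5th with peaks of a fold of at least 2.

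For H3K27ac, neuroblast identity was the group that stood apart, at the 99.98th percentile, with mean cover of 18.5% in the control and 22.0% in the knockdown (3.54 points, against a random mean of -7.59). Cover was higher in the knockdown for 13 of its 26 genes and lower for 10. Among the higher were mira (1.15 and 2.40 kb), pins (0.795 and 1.62 kb), pon (none and 1.15 kb) and par-6 (none and 0.824 kb). So were the proneural gene ase (none and 0.472 kb), nerfin-1 (0.570 and 1.12 kb) and pros (14.4 and 17.1 kb). Lower were grh (11.7 and 8.02 kb), dpn (0.533 and 0.044 kb) and insc (5.25 and 3.82 kb). The random sets were not matched on chromosome arm. The H3K27ac covered ratio was 0.821 on X and 0.801 on 4, against 0.625 to 0.663 on the other arms. Of the genes named here, pon, par-6 and ase lie on X, and pros lies on 3R. How far the arm enters this percentile was not tested. As deposited, lower cover in the knockdown was general, as in housekeeping genes (39.8 and 29.6%, 53.7th percentile). Among markers of other cell types it was 20.4 and 9.33% for muscle and mesoderm and 22.0 and 11.5% for gut, blood and fat, at the 9.55th and the 8.90th percentile. Examples are tin (1.95 and 0.376 kb) and sls (15.3 and 5.10 kb) in muscle, and the blood cell genes Hml (4.89 kb and none) and lz (0.706 kb and none). The means were 27.8 and 18.4% for glia (52.3th), 22.8 and 15.0% for epidermis and trachea (59.3th), and 16.1 and 11.7% for neuron markers (80.1th), so these 3 differed no more than matched genes. Spatial patterning genes averaged 21.2 and 13.8%, temporal genes 18.4 and 16.6%, Hox genes 13.6 and 9.27%, Notch pathway genes 34.8 and 27.5%, Polycomb group genes 34.6 and 26.5%, and Trithorax and acetylation genes 36.0 and 27.6%. They were 30.8 and 22.6% for cut and cohesin, where SMC1 had 2.81 and 0.521 kb and SA1 1.37 and 1.49 kb, 25.8 and 25.0% for the cell death machinery, and 2.45 and 2.53% for the cell death activators. The 15 groups other than neuroblast identity lay between the 8.90th and the 94.2th percentile. With peaks of -log10 q of at least 2, neuroblast identity lay at the 74.7th percentile, and with peaks of a fold of at least 2 at the 95.1th.

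**Figure D4:**
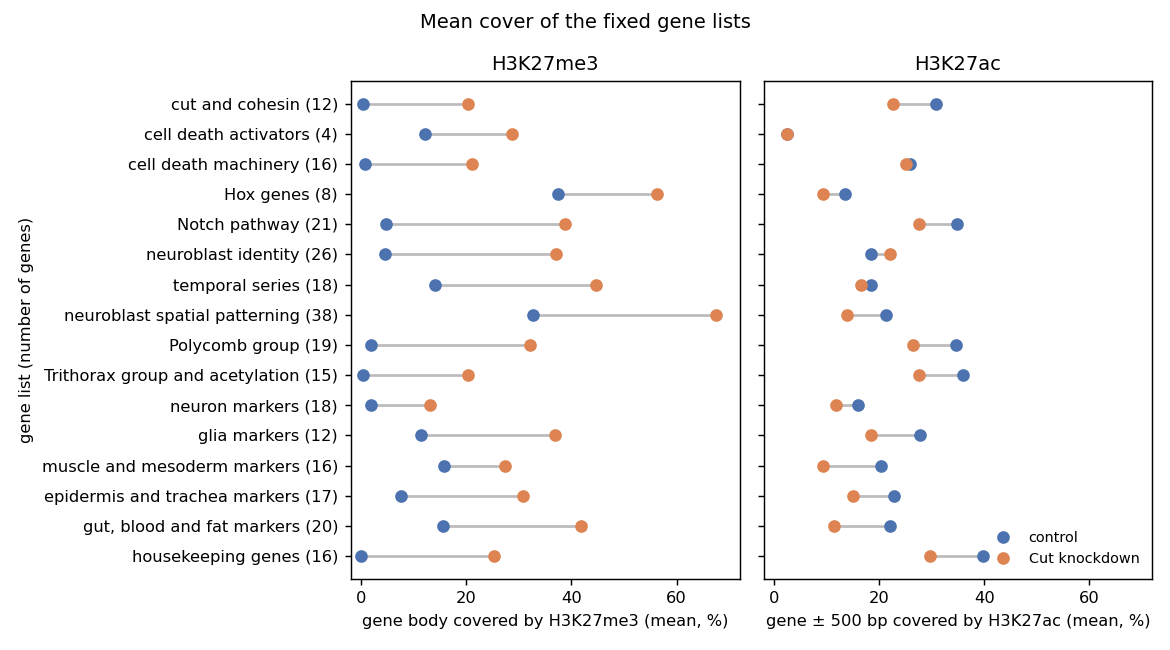
Mean share of each gene covered by H3K27me3 (left, gene body, %) and by H3K27ac (right, gene with 500 bp either side, %) for the 16 gene groups, with the number of genes in parentheses. Points are the control and the knockdown library, joined by a line. H3K27me3 means were higher in the knockdown in all 16 groups as deposited, and the H3K27ac mean of neuroblast identity genes was 18.5% in the control and 22.0% in the knockdown.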

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

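The tests of the calling threshold, of acetylated chromatin, of windows along the arms and of other cell types' markers, and the lists without peaks or bases shared with H3K27ac, were chosen only after the results were seen. So were the bound of 1 median control peak width used for the weak peak test at the cell death locus and the look at H3K27ac peak widths and folds at the same covered length.

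Peaks on the Y chromosome lie outside the comparisons. There were 79 in the control and 194 in the knockdown for H3K27me3, and 294 and 251 for H3K27ac. The covered length of the 2 marks differed in opposite directions between the genotypes, with a knockdown to control ratio of 4.16 for H3K27me3 and 0.667 for H3K27ac as deposited, but not with peaks of a fold of at least 2, where the ratios were 6.37 and 1.65. For H3K27ac that bound kept 32.6% of control and 80.3% of knockdown peaks and so favours the knockdown. For H3K27me3 it kept 18.5% and 27.8%. The difference between the marks was not tested, since each group had 1 library.

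For the longer H3K27me3 list of the knockdown, a laxer threshold would bring the ratio down once both lists are held to a fold of at least 2, but the ratio was then 6.37. That bound kept 18.5% of control and 27.8% of knockdown peaks and so favours the knockdown. Peaks with -log10 q of at least 2, which were 22.3% and 27.9%, gave a ratio of 4.82. The ratio thus fell under neither bound, though neither kept equal shares of the lists. An earlier test of the same idea, the lower median fold of knockdown-only peaks (1.88 against 2.05 for shared ones), was set aside because unshared peaks had the lower median in all 4 lists. Signal from acetylated or accessible chromatin in the knockdown H3K27me3 library may account for part of the added length. Of the bases covered only in the knockdown, 52.3% lay in control H3K27ac peaks, and the highest of 1000 circular shifts gave 18.4%. The shifts do not keep peaks near genes, so 2 lists that both lie on genes can exceed them without this cause. At peaks with -log10 q of at least 2 the overlap was 3.78 times the shifts in the control and 3.84 times in the knockdown. The gap between the genotypes stayed at the same covered length (1.38 and 2.18 times) and with peaks of a fold of at least 2. Its absence under 1 bound therefore does not argue against such signal. The knockdown list stayed the longer when bases inside H3K27ac peaks were left out. That keeps the other bases of the same H3K27me3 peaks, so it cannot exclude such signal. Leaving out the overlapping peaks whole lowered the ratio further, as given above. Replacement of H3K27ac by H3K27me3 at the newly covered genes stays open: their H3K27ac cover differed by -11.6 points between the genotypes, against -20.6 points in genes matched on control H3K27ac, but they were picked by knockdown H3K27me3 that lies largely on H3K27ac, so a test planned to exclude replacement could not. Read depth and the knockdown of Cut itself stay open, since both are tied to the same library. The labels give both marks the same catalogue number. In the control, H3K27me3 covered less than H3K27ac along the arms (4.68 and 22.2 Mb) but more of the bithorax region (113 and 41.6 kb) and the Antennapedia region (87.9 and 49.3 kb). In the knockdown these regions had 188 against 30.7 kb and 159 against 36.8 kb. These values argue against 1 antibody for both marks in the Hox regions. How specific each antibody was stays open.

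At the cell death locus, the lower H3K27me3 cover between grim and rpr was set beside windows of the same length and like control cover, with both lists at the same covered length; a count on the lists as deposited (2.03% of 395 windows with less cover in the knockdown) was set aside, since the longer knockdown list fixes its outcome. A general difference in detection cannot be told apart from a local one, because 11 of 105 windows without overlap (10.5%, 5.35 to 18.0%), and 36 of all 395 (9.11%), had a difference at least as low as the -11.9 kb of the interval, and the bound of 10%, set after the data were seen, lies inside that range. Weak peaks near the threshold cannot be told apart from a true difference: with peaks of -log10 q of at least 2 the difference was -0.576 kb of 6.41 kb in the control, less than 1 median control peak width of 815.5 bp. Extra copies of rpr in the knockdown embryos stay open too: the knockdown H3K27ac list covered 0% of the high rpr peak, but the rise needed, 1.80 times the control fold, is under the lowest fold of the knockdown H3K27ac peaks from hid to skl (1.99, though 1.45 along the arms), so a test planned to exclude them could not. Input DNA was the control. If it came from the same embryos, extra copies would raise it too, and the ratio of folds need not measure copies. An effect of Cut on H3K27me3 between grim and rpr is a hypothesis that these 2 libraries leave open, as the interval could also vary between any 2 such sorts.

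The higher H3K27ac cover of neuroblast identity genes in the knockdown was the highest of 32 list percentiles. Narrower peaks of higher fold in that list cannot be told apart from it, although the gene group stayed at the 98.9th percentile (6.41 points, 3.54 as deposited) with both lists at the same covered length, a result planned to exclude them. That plan was wrong, since the reduction left the median widths further apart, at 673 and 432 bp against 625 and 432 bp as deposited, and the median folds at 2.01 and 2.13. A larger share of neuroblast nuclei in the knockdown sort would lower the markers of the other cell types, and their 62 genes differed by -9.82 points, at the 9.75th percentile of matched sets, which neither shows nor excludes it, and the sort was at least 50% pure in the labels, so such a difference in purity could arise. The random sets were not matched on chromosome arm, and how far the higher H3K27ac covered ratio of X (0.821) enters was not tested. An effect of Cut on these genes was not tested apart from these.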

How the results depend on the processing

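Choices were changed one at a time; the lists without peaks or bases shared with H3K27ac and the calls at gene ends were tests chosen only after the data were seen. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out in turn. The 16 settings gave 302 further values. Of the values that answer a comparison, 46 stayed close to the value as deposited, 67 moved and 13 changed direction, and of the percentiles of single gene lists 144 stayed close, 27 moved and 5 changed sides. The cause was not tested, except that a stricter list or bound takes in fewer peaks and genes by construction. The plans to use the outermost 5' end of a gene and a window around transcript starts were not run, since the gene table holds no strand, and calls at either gene end took their place. Read depth, which is unknown, limits each comparison of covered length. The grim to rpr difference of H3K27me3 stayed below 0 in each setting tried. The same covered length, which trims the knockdown list alone for this mark, could only lower it.

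With peaks of -log10 q of at least 2, genes with H3K27me3 only in the knockdown numbered 517 and only in the control 14, and 64.7% of control and 12.3% of knockdown H3K27me3 peaks were shared. Genes with H3K27ac only in the knockdown numbered 2557, and 28.2% of control and 30.9% of knockdown H3K27ac peaks were shared. The H3K27me3 difference was -0.576 kb from grim to rpr and 133.8 kb in the bithorax region, and the H3K27ac difference 0 kb, -5.33 kb and, in the Antennapedia region, 1.57 kb. The control H3K27me3 overlap with H3K27ac was 3.78 times the shifts. For H3K27me3, 2 lists lay in the top 2.5% of random lists and 0 in the bottom 2.5%, with Hox genes at the 53.5th, and for H3K27ac 0 and 1.

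With peaks of a fold of at least 2, the covered ratio was 6.37 for H3K27me3 and 1.65 for H3K27ac. For H3K27ac this bound kept 32.6% of control and 80.3% of knockdown peaks and so favours the knockdown. For H3K27me3 it kept 18.5% and 27.8%. Gains and losses were 557 and 11 genes for H3K27me3 and 4438 and 610 for H3K27ac, and the share of knockdown peaks shared was 9.46% and 26.9%. The H3K27me3 difference was -3.77 kb from grim to rpr and 138.2 kb in the bithorax region. The H3K27ac difference was 1.03 kb from grim to rpr, 3.16 kb from hid to skl, 10.8 kb in the bithorax and 18.0 kb in the Antennapedia region. For H3K27me3, 0 lists lay in the bottom 2.5%, with muscle and mesoderm markers at the 56.5th, and for H3K27ac 0 lay in the top 2.5%.

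With the longer list reduced to the same covered length, gains and losses were 260 and 197 genes for H3K27me3 and 2528 and 929 for H3K27ac. Only the knockdown H3K27me3 list and the control H3K27ac list were trimmed. Differences in covered kb could therefore only fall for H3K27me3 and only rise for H3K27ac. Shared were 30.2% of control and 32.7% of knockdown H3K27me3 peaks, and 62.6% and 45.5% of H3K27ac peaks. The H3K27me3 difference was -11.9 kb from grim to rpr, -13.4 kb from hid to skl, 44.8 kb in the bithorax and 38.9 kb in the Antennapedia region, and that of H3K27ac 1.42 kb from hid to skl, 0.66 kb and 1.64 kb. For H3K27me3, 0 lists lay in the bottom 2.5%.

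Without H3K27me3 peaks that overlap H3K27ac, the covered ratio was 1.32, gains and losses were 54 and 27 genes, and 27.3% of control and 16.9% of knockdown peaks were shared. The differences were -6.76 kb from hid to skl, -1.22 kb in the bithorax and -3.83 kb in the Antennapedia region. For this mark 0 lists lay in the top 2.5% and 1 in the bottom 2.5%, with the Polycomb group at the 4.56th. With H3K27me3 bases outside H3K27ac peaks only, the ratio was 2.40, and the differences were -0.563 kb from hid to skl and 34.1 kb in the Antennapedia region.

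Requiring 25% of the gene body gave 4223 H3K27me3 gains and 114 losses, and 75% gave 841 and 30. A peak within 500 bp of either gene end gave 6899 and 201. At least 50% of the extended span gave 472 H3K27ac gains. An overlap of at least 50% of the peak left 44.3% of control and 7.51% of knockdown H3K27me3 peaks shared, and 34.3% and 52.7% of H3K27ac peaks. Merging peaks less than 1 kb apart gave 60.5% and 68.1% for H3K27ac. Genes called for both marks in the knockdown were 1.13 times the product of the shares. With random lists matched on length only, 7 H3K27me3 lists lay in the top 2.5% and 0 in the bottom 2.5%, with Hox genes at the 88.9th, and with unmatched random lists 3 and 0, with Hox genes at the 52.1th.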

Other observations

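The strongest and widest peaks of each list were looked up after their values were seen, and many of them, the highest H3K27me3 peak of either genotype included, overlapped no protein-coding gene. By deposited fold, the control H3K27me3 list was led among genic peaks by ham (2L:18781262-18781523, 2.71), Ets65A (2.68), pdm2 (2.64), dati (2.62) and bsh (2.60), all transcription factor genes. The knockdown list was led among genic peaks by rpr (3.38), TfAP-2 (3L:21587695-21588184, 3.12), CG9380 (3.08) and dlp, a glypican gene (3.07). The highest peak of the knockdown list, at 2R:13016892-13017326 with a fold of 3.61, overlapped no protein-coding gene. A site near the end of X that overlapped no protein-coding gene had high folds in both genotypes, 2.85 at X:23020408-23021827 in the control and 3.20 at X:23020517-23021820 in the knockdown. Among H3K27me3 peaks on genes, the widest of the knockdown list were 21747 bp over Optix (2R:8020271-8042017), an eye and brain regulator, and 18975 bp over Poxn and its neighbours (2R:15824179-15843153), while the widest genic control peak spanned 8484 bp at opa (3R:4855753-4864236).

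The highest knockdown H3K27ac folds lay at dco, a casein kinase gene (5.31), mod(mdg4), which encodes insulator proteins (4.42), and RpL28 (4.11). At l(1)G0289 the fold was 3.43 in the control, the highest of that list, and 4.07 in the knockdown. The widest genic H3K27ac peak of the knockdown list spanned 9097 bp at tara (3R:16250540-16259636) with a fold of 2.79. Wide peaks near the start of the 3R sequence were present for both marks, up to 46280 bp in the knockdown H3K27me3 list and 36398 bp in the control H3K27ac list.

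Windows of the grim to rpr length were compared along the arms, with the lists as deposited, of which that of the knockdown is the longer. Of 13315 windows that did not overlap the interval, 334 (2.51%) had less, and 4 had a difference at least as low. These 4 overlapped each other between 2R:3250001 and 2R:3373117, where the lowest window had 8.38 kb in the control and 1.44 kb in the knockdown. These counts do not show that the interval is rare. The control list covered 16.4% of the interval but 3.50% of the arm span, and a window with little control cover cannot fall as far. Among windows of like control cover, with both lists at the same covered length, 11 of 105 were as low as the interval.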
